A study of Mus musculus with 6 samples.

How the data were processed

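RNA of whole testis from wild-type and Ppp6r3 cKO mice on postnatal day 9 was compared, with 3 libraries per group. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected with oligo(dT) beads and stranded libraries were made with a KAPA kit. Per the series' design text, paired-end reads were aligned to the mm10 mouse genome with HISAT2 2.0.5. The submitters' processing notes also name DESeq2. The tool that counted fragments per gene, its strand setting and the annotation release were not given in the sources used here, so overlapping and antisense genes may share reads, as may near-identical copies such as globin and ribosomal protein genes and pseudogenes.

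The deposited table is named as raw counts, but its values are FPKM (fragments per kilobase of exon, scaled to the fragments of the library), with fractions throughout and 54532 genes. Columns were matched to samples by their names. Each deposited FPKM value times the exon length of the gene in GENCODE M21 was a whole multiple of 1 step per library, within a tolerance of 0.01. This held in every library for 31625 of the 32589 genes above 0 (97.0%), and a further 947 genes were whole with another length. The 17 genes that were not recovered were left out. The steps gave 15970908 to 16606868 fragments per library. The fragments recovered over the listed genes summed to 101.35% to 103.16% of that number, so the denominator was not exactly their sum, and the depth is an inference from the values.

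The test planned before the data were examined was a count test with edgeR, which was not used because the deposited values are not counts. Nor was it run on the recovered fragments, which were tested with voom as an alternative. In its place, log2(FPKM + 0.1) was tested with limma 3.58.1 in R 4.3.3 (moderated variance with a trend and robust estimation, 2-sided), and p-values were adjusted by Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Fold changes are on the log2(FPKM + 0.1) scale and understate the change of low genes. The deposited scaling was kept: median-ratio factors ran only from 1.0006 to 1.0049. Genes with at least 10 recovered fragments in at least 3 libraries were tested. That minimum was listed beforehand as an alternative and became the main filter only after a first run, with a minimum of 0.5 FPKM, had let short RNAs resting on a few fragments take the largest fold changes. The result with 0.5 FPKM is given with the other alternatives.

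The 30 gene lists (783 genes) were fixed before the data were examined. Of their genes, 774 were found by GENCODE symbol, 6 through RefSeq and 3 were not found. The 29 lists with at least 5 tested members were tested with camera (preset correlation 0.01, adjusted over the lists), again with an estimated correlation, and with fry. Ppp6r3 was left out of the list tests. Named genes followed a rule set beforehand: the phosphatase 6 subunits, the 8 largest changes in each direction among passing genes with non-overlapping groups, a mean log2 CPM of at least 0 and a gene name, up to 3 passing members of each list with the largest change (or the 2 with the smallest p where none passed), and Kit, Stra8, Gfra1, Zbtb16, Sycp3, Ddx4, Sox9, Cyp11a1 and Acta2. Of predicted or unnamed gene models, 198 met the other conditions for the largest changes, of which 64 rose and 134 fell. The 4 meiotic genes that did not pass, Gm6038, and Col4a1, Col15a1 and Lamc3 in the closing section, were named after their values were seen. Some genes that the rule names are not reported here.

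On data simulated from these libraries' means, with 200 of 17666 genes changed, limma recovered 78.8% of genes changed 1.5-fold, 78.8% changed 2-fold and 98.5% changed 4-fold, and 9 of 180 calls were false. None of 20 random lists of unchanged genes was called. The simulation drew genes independently of each other, with a common dispersion (0.00103) and no GC trend. It therefore cannot show how often genes or lists are falsely called in the real libraries. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.23 to 4.35), so each library was counted once. GC content was the length-weighted mean over a gene's GENCODE M21 transcripts, known for 17659 of the tested genes. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10. Intervals of differences between list medians came from 10000 resamples of the genes, which are not independent replicates. With 3 against 3 libraries an exact permutation test of 1 gene cannot go below p = 0.1. Alternatives changed the model (voom), scaling, filter, pseudocount, robust estimation, replicate block, GC and length (natural splines with 5 degrees of freedom), threshold and libraries. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used.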

Results

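Messenger RNA was measured in whole testis of mice on postnatal day 9, when the first germ cells of the tubules are entering meiosis. The 6 libraries were 3 of wild-type testis and 3 of testis with a conditional knockout of Ppp6r3, called Ppp6r3 cKO below. Ppp6r3 encodes a regulatory subunit of protein phosphatase 6. The labels name neither the Cre line nor the deleted exons. The deposited values are FPKM, and the steps between them gave back the depth: 15970908 to 16606868 fragments per library, with 25841 to 26642 genes above 0. The series title places the study in mRNA translation during spermatogonial differentiation, and the comparison asked which transcripts of the testis differed without Ppp6r3. Nothing in the labels says that the 3 samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

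Ppp6r3 itself, the targeted gene (ENSMUSG00000024908, chromosome 19, 3454928 to 3575749 on the minus strand of mm10, protein-coding), stood at 21.025 ± 0.257 FPKM in wild type and 15.4 ± 0.458 FPKM in Ppp6r3 cKO (SD, n = 3 each). It fell by 0.45 on the log2 scale (SE 0.042, limma adjusted p = 0.000697), to 0.73 of the wild-type level, and all 3 Ppp6r3 cKO libraries lay below all 3 wild-type libraries. The value covers the whole gene in whole tissue, so it does not give the level in the cells where the gene was deleted. Of the other phosphatase 6 subunits, the catalytic subunit Ppp6c fell by 0.14 (adjusted p = 0.0445; Ppp6c was at -0.084, not passing, after the GC and length correction) and the ankyrin repeat subunit Ankrd52 rose by 0.26 (adjusted p = 0.0208). The Ppp6c call was lost without any single library and the Ankrd52 call without 4 of the 6. Ppp6r1 (log2 fold change 0.06), Ppp6r2 (-0.15), Ankrd28 (0.02) and Ankrd44 (-0.11) did not pass, though Ppp6r2 was called lower with voom and after the GC and length correction.

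**Figure D1:**
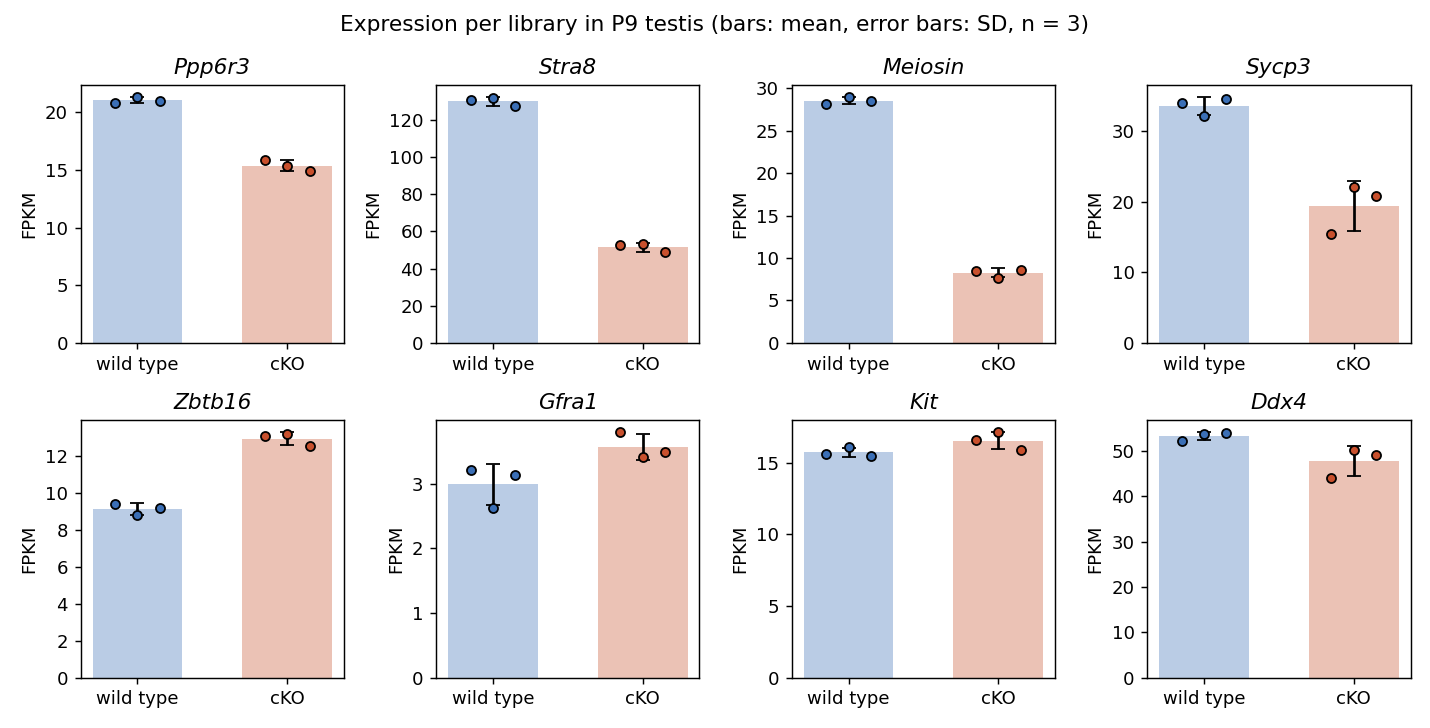
Expression in FPKM (y axis) of 8 genes in the 3 wild-type libraries (blue) and the 3 Ppp6r3 cKO libraries (orange); points are libraries, bars are means and error bars are SD. Stra8 averaged 129.9 FPKM in wild type and 51.4 in Ppp6r3 cKO, Zbtb16 averaged 9.14 and 12.96 FPKM, and Kit averaged 15.7 and 16.5 FPKM.

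Genes of meiotic entry and prophase fell together in Ppp6r3 cKO testis. Of 47 tested members of that list, 43 fell, none rose and 4 did not pass (46 fell when adjusted over the list alone), with a median log2 fold change of -0.80. Stra8, the retinoic acid-induced gene needed to start meiosis (chromosome 6, 34920163 to 34939344), went from 129.9 ± 2.23 to 51.4 ± 2.37 FPKM (SD, n = 3 each; log2 fold change -1.34, SE 0.043, limma adjusted p = 5.1e-06). Meiosin, its partner in transcription (chromosome 7, 19099046 to 19118368), went from 28.5 to 8.25 FPKM (log2 fold change -1.78). Spo11, which makes the DNA breaks of meiotic recombination, fell by 1.80, the recombination gene Meiob by 2.10, and Sycp3 of the synaptonemal complex by 0.80. The 4 members that did not pass were Ythdc2, Mei4, Rnf212 and Mlh3. The list's camera test gave an adjusted p of 4.2e-41, and an adjusted p of 0.0133 with an estimated correlation, the only list called that way.

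Markers of undifferentiated spermatogonia were higher. Of 26 tested, 9 rose, none fell and 17 did not pass (11 rose when adjusted over the list alone), with a median of 0.26, or 0.17 for undifferentiated spermatogonia without wild-type replicate 2, where the list stayed called. Zbtb16, a transcription factor of spermatogonial stem and progenitor cells, went from 9.14 ± 0.308 to 12.96 ± 0.356 FPKM (SD, n = 3 each; log2 fold change 0.50, limma adjusted p = 0.000902). Egr4 rose by 0.49 and Spry4 by 0.68 (0.44 with a pseudocount of 1), while Gfra1, the GDNF receptor, had a log2 fold change of 0.25 that did not pass (adjusted p = 0.129). Whether the transcripts that rose came from spermatogonia was not tested in this whole tissue. The list was called (camera adjusted p = 5.9e-05), with an adjusted p of 0.106 with an estimated correlation. Among 16 genes of differentiating spermatogonia, 5 rose, 5 fell and 6 did not pass, with a median of -0.02 and a mean of -0.24. The list was not called by camera, while fry called it down (adjusted p = 0.0251). The fry test asks whether a list's genes move on balance one way and does not compare them with other genes. Prss50 fell by 0.93, and Stra8 and Prdm9 (log2 fold change -1.43), which also stand in the meiotic list, fell. Kit, the receptor that marks differentiating spermatogonia, had a log2 fold change of 0.07 (adjusted p = 0.333).

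Of 20 later spermatocyte genes listed, only 10 met the filter and were tested. Of these, 4 fell and 6 did not pass (median -0.25, camera adjusted p = 0.0362, and adjusted p = 0.199 with an estimated correlation). Ybx2 fell by 1.05. The list was not called without wild-type replicate 1 or with no low-value filter. Of 26 genes shared by germ cells and of the piRNA pathway, 6 fell, 1 rose and 19 did not pass, with a median of -0.11 (camera adjusted p = 0.0568, not called; fry adjusted p = 0.053). Camera called this list down without wild-type replicate 1 or Ppp6r3 cKO replicate 2, with voom, with no filter, with the replicate number as a block and after quantile normalization. Fkbp6 and Mov10l1 each fell by 0.28. The germ cell helicase Ddx4 had a log2 fold change of -0.16 that did not pass (adjusted p = 0.0858), though voom on recovered fragments called it lower. Of 18 spermatid genes listed, only 8 were tested. Oaz3 fell (log2 fold change -0.83, or -0.23 with a pseudocount of 1) and 7 did not pass. The list was called by neither test.

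**Figure D2:**
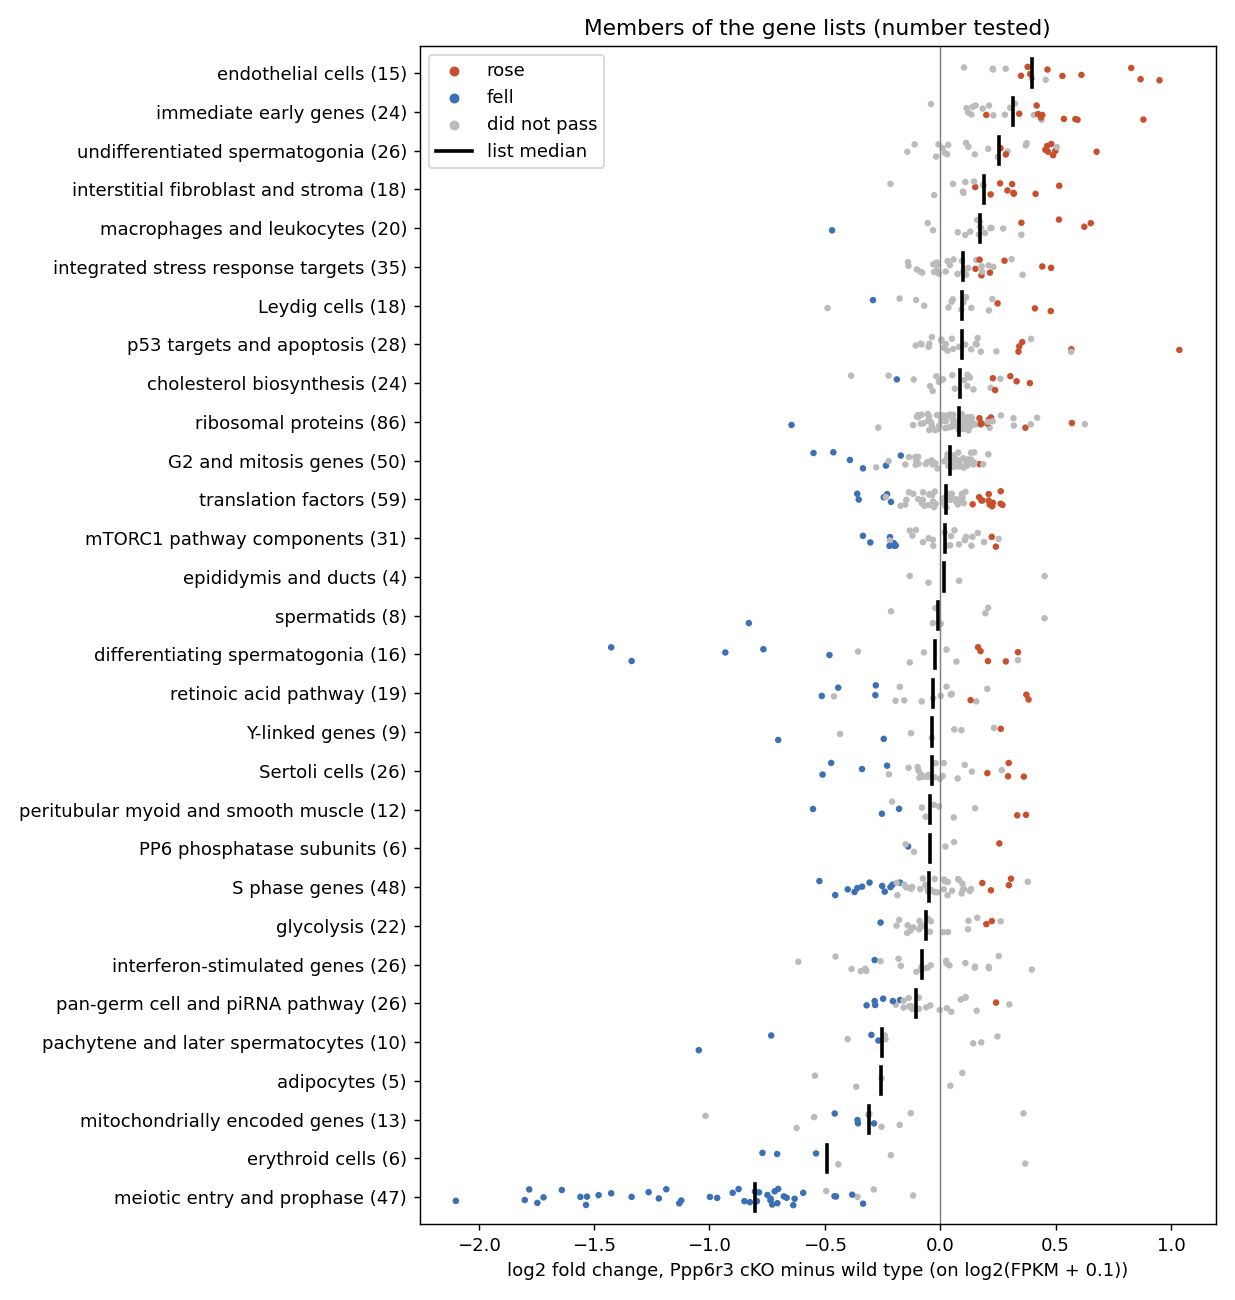
Log2 fold change (x axis, Ppp6r3 cKO minus wild type) of each tested member of the 30 gene lists (y axis, number tested in brackets); each point is a gene, orange if it rose, blue if it fell and grey if it did not pass, and black bars are list medians. The meiotic list lies lowest with a median of -0.80 and the endothelial list highest with 0.40.

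Among the other cell types of the testis, endothelial markers were the highest: 9 of 15 rose, none fell and 6 did not pass, with a median of 0.40 (camera adjusted p = 4.0e-08, and adjusted p = 0.0992 with an estimated correlation). Tie1, an endothelial receptor, went from 2.07 to 4.08 FPKM (log2 fold change 0.95), Vwf rose by 0.87 and the tight junction gene Cldn5 by 0.83. Of 18 interstitial fibroblast and stroma genes, 9 rose and 9 did not pass (median 0.19, camera adjusted p = 7.5e-07, and adjusted p = 0.0655 with an estimated correlation), among them the collagens Col5a1 (0.52) and Col1a2 (0.41). Of 20 macrophage and leukocyte genes, 4 rose, 1 fell and 15 did not pass (median 0.17, camera adjusted p = 0.0018, and adjusted p = 0.0992 with an estimated correlation). Lyz2 rose by 0.65 and Adgre1 by 0.62. Erythroid genes were lower: 3 of 6 fell and 3 did not pass (median -0.49, camera adjusted p = 0.00313, and adjusted p = 0.106 with an estimated correlation). With no low-value filter the median of erythroid cells was -0.21 and the list stayed called. The 3 that fell were Hbb-bs (-0.71), Alas2 (-0.54) and Hba-a1 (-0.77), and the globin genes have near-identical copies whose reads may be split.

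Sertoli, Leydig and myoid lists were not called by camera, while fry called the Leydig list up (adjusted p = 0.0188) and the myoid list down (adjusted p = 0.0251). Camera called the Leydig list up with voom, with no filter and with the minimum of 0.5 FPKM. In the main fit its camera adjusted p was 0.0777, and 0.43 with an estimated correlation. Of 26 Sertoli genes 4 rose and 4 fell, with Amh up by 0.36, Gata1 down (log2 fold change -0.47), Rhox5 down (-0.51) and Sox9 at 0.02 (not passing). Of 18 Leydig genes 3 rose and 1 fell. Dlk1 rose by 0.48, Thbs2 rose by 0.41, Ren1 fell by 0.29 and Cyp11a1 had a log2 fold change of 0.06 (not passing). Of 12 peritubular myoid and smooth muscle genes 2 rose and 3 fell, and Acta2 fell by 0.25. The adipocyte list (none of 5 passing) was called by neither test, and the epididymis list had 4 tested members, too few for a test, none of which passed.

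Immediate early genes, which respond within minutes to stimuli, were higher: 10 of 24 rose, none fell and 14 did not pass (median 0.31, camera adjusted p = 7.8e-08, and adjusted p = 0.0699 with an estimated correlation). Egr1 rose by 0.60 and Klf4 by 0.59. The labels do not say how the tissue was handled before RNA was taken, so handling was not separated from genotype. Of 28 p53 targets and apoptosis genes, 5 rose and 23 did not pass (median 0.10, camera adjusted p = 0.00313, and adjusted p = 0.0992 with an estimated correlation). Pmaip1, which encodes the pro-apoptotic protein NOXA, went from 1.95 to 4.09 FPKM (log2 fold change 1.04), and Bbc3, which encodes PUMA, rose by 0.57. Of 48 S phase genes 12 fell, 4 rose and 32 did not pass (median -0.05, camera adjusted p = 0.0429, and adjusted p = 0.23 with an estimated correlation), and Ccne2 was among those that fell (-0.52). The S phase list was not called without wild-type replicate 1 (median of S phase genes -0.031) or 3, without Ppp6r3 cKO replicate 1 (-0.031), with the replicate number as a block or after the GC and length correction. Of 50 G2 and mitosis genes 6 fell, 1 rose and 43 did not pass; Bub1 fell by 0.55 and Mki67 by 0.46, and the list was called by neither test, with a median of 0.04 and a mean of -0.02.

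For the translation machinery, 10 of 86 ribosomal protein genes rose, 1 fell and 75 did not pass (median 0.08, camera adjusted p = 0.00314, and adjusted p = 0.59 with an estimated correlation). Over the list alone, 3 rose and 1 fell, and fry did not call the list (adjusted p = 0.157). The median of ribosomal proteins was 0.053 without wild-type replicate 3 (not called), 0.055 after quantile normalization and 0.13 after the GC and length correction (called in both). Of 59 translation factors 12 rose and 5 fell, with Eif2s2 at -0.36, Eif2b3 at -0.35 and Eif2s3x at 0.27. Camera did not call the list, and fry called it up (adjusted p = 0.0251). Of 35 targets of the integrated stress response 7 rose and 28 did not pass (median 0.10, camera adjusted p = 0.041, and adjusted p = 0.43 with an estimated correlation), including Stc2 (0.48) and the amino acid transporter Slc7a5 (0.28). The integrated stress response list was not called without wild-type replicate 3, without Ppp6r3 cKO replicate 1 (median 0.037), after the GC and length correction or after quantile normalization. Of 31 mTORC1 pathway genes 2 rose and 7 fell, and neither test called the list. Of 24 cholesterol synthesis genes 5 rose, 1 fell and 18 did not pass (median 0.08, camera adjusted p = 0.041, and adjusted p = 0.387 with an estimated correlation), with Srebf2 at 0.30, and this list was not called without wild-type replicate 1 or 3 or Ppp6r3 cKO replicate 1. Of the 13 mitochondrially encoded genes 5 fell and 8 did not pass (median -0.31, camera adjusted p = 0.0018, and adjusted p = 0.43 with an estimated correlation). This list was not called after the GC and length correction, with a median of -0.15, nor by fry (adjusted p = 0.0627). Of interferon-stimulated genes 1 of 26 fell, and fry called the list down (adjusted p = 0.0357) while camera did not call it. Called by neither test were the lists of retinoic acid pathway genes (3 rose and 4 fell of 19, with Cyp26b1 at 0.38 and Rbp4 at -0.44), glycolysis (2 rose and 1 fell of 22), Y-linked genes (1 rose and 2 fell of 9) and the phosphatase 6 subunits (1 rose and 1 fell of 6).

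Over all 17666 genes tested, 2735 changed: 1352 rose and 1383 fell (limma, adjusted p under 0.05). After the GC and length correction 3356 changed, and more rose (1824) than fell (1532). Most changes were small, with a median rise of 0.30 and a median fall of -0.36, and 10 genes rose and 118 fell at least 2-fold. Of those 118, 17 belonged to the meiotic list. Among passing genes with a name in GENCODE, a mean log2 CPM of at least 0 and groups that did not overlap, the largest falls were Gfy (-2.41), Meiob (-2.10), Prss41 (-1.93), Tpbgl (-1.83), Spo11 (-1.80), Gal3st1 (-1.78), Msh5 (-1.74) and Spata22 (-1.72). Of the predicted models left out there, 2 fell by more than Spata22: Meiosin (-1.78), which GENCODE lists under a model name, and the processed pseudogene Gm6038 (-2.41). Under the same limits, which left out rises of genes with fewer fragments, the largest named rises were Pmaip1 (1.04), Slc15a2 (1.005), Tie1 (0.95), Klhl30 (0.95), Cbln4 (0.92), Trem2 (0.89), Vwf (0.87) and Sowahb (0.86). A pseudocount of 1 made several of these changes over 1.5 times smaller, among them Gfy (-1.55), Prss41 (-1.28), Tpbgl (-1.14), Slc15a2 (0.51), Klhl30 (0.58), Cbln4 (0.51), Trem2 (0.49), Vwf (0.44) and Sowahb (0.25). The groups did not overlap in 36.9% of tested genes, where chance gives 10%.

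Leaving out wild-type replicate 1, 2 or 3 lowered the count of changed genes to 1619, 1234 and 1331. The count of genes that rose at least 2-fold was 21 without wild-type replicate 1 and 17 without replicate 2. Over all settings it went from 1 (pseudocount of 1) to 34 (voom), and falls of at least 2-fold from 39 to 217 with the same 2 settings. The calls of Rhox5, Oaz3 and Sowahb and of the later spermatocyte, S phase, cholesterol, integrated stress response and ribosomal lists were each lost without at least 1 library. The preset-correlation list test also called up to 7 lists when libraries of both genotypes were mixed in each group. There the ribosomal list reached a camera adjusted p of 3.1e-10 and the mitochondrial list 1.2e-06, both below their values between genotypes. Part of a genotype difference remains between such unevenly mixed groups, so calls there do not by themselves show that the test is wrong.

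**Figure D3:**
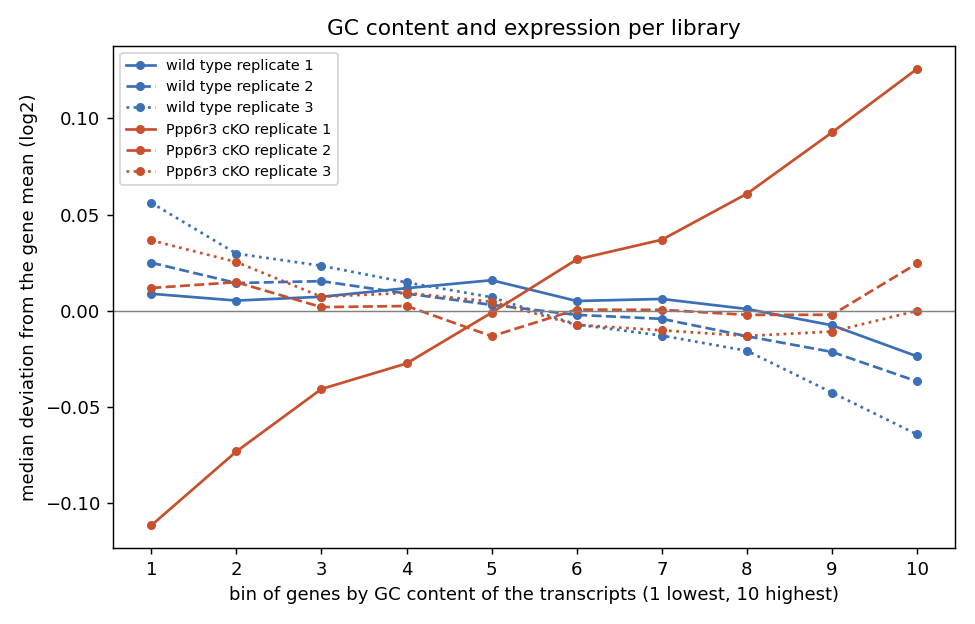
Median deviation of each library from the gene mean (y axis, log2) over 10 bins of the tested genes by GC content (x axis, equal numbers of genes); lines are libraries, blue wild type and orange Ppp6r3 cKO. Ppp6r3 cKO replicate 1 runs from -0.112 in the lowest bin to 0.126 in the highest.

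Ppp6r3 cKO replicate 1 stood apart in its GC content: its median deviation ran from -0.112 in the lowest of 10 bins of genes by GC to 0.126 in the highest, and wild-type replicate 3 ran from 0.056 to -0.064. The median log2 fold change went with it, from -0.05 to 0.09. The direction of the called genes did too: 41 rose and 160 fell in the lowest bin, and 278 rose and 71 fell in the highest. Without Ppp6r3 cKO replicate 1, 2397 genes changed.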

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

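Chosen after seeing the data were the pseudocounts of 0.01 and 1, the minimum of 0.5 FPKM, the GC and length correction and quantile normalization, and the test and main filter were themselves set after the unit was known. DESeq2, and edgeR with its own scaling and filter, were planned and not run. The deposited values are FPKM, and the recovered fragments, on which both could have been run, were tested with voom only. No alternative reversed a called result. Ppp6r3 stayed called, from -0.47 to -0.43, as did the meiotic list, from -0.84 to -0.74. Voom on recovered fragments called 4069 genes, with 2105 that rose and 34 up and 217 down at least 2-fold. With no filter 1508 changed (740 rose, 768 fell, 31 rose at least 2-fold). At an adjusted p under 0.01, 888 changed (418 rose, 470 fell; 5 and 78 at least 2-fold). At least 2-fold rises numbered 22 with a pseudocount of 0.01, 1 with a pseudocount of 1 (and 39 falls) and 21 with the minimum of 0.5 FPKM, which called 2442 genes. The cause of these differences was not tested, except that fewer genes pass a stricter threshold.

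Without 1 library, 1234 to 2397 genes changed, 597 to 1121 rose and 637 to 1276 fell, and 7 to 21 rose at least 2-fold. Without wild-type replicate 1, 2 or 3 the counts were 1619, 1234 and 1331; without Ppp6r3 cKO replicate 2, 898 rose. Fewer libraries were then tested. List medians ranged from -0.29 to -0.20 for later spermatocytes, from 0.053 to 0.094 for ribosomal proteins, from 0.037 to 0.15 for the integrated stress response, from -0.060 to -0.031 for S phase and from 0.065 to 0.099 for cholesterol, and each of these lists lost its call without at least 1 library. Of 93 named genes called, 65 kept their call without each library and 28 lost it without at least 1.

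With an estimated correlation, 0 lists were called up and 1 down, against 9 and 5. The lists that lost their call had these medians, the same as in the main test: undifferentiated spermatogonia 0.26, later spermatocytes -0.25, stroma 0.19, macrophages 0.17, endothelial 0.40, erythroid -0.49, ribosomal 0.083, integrated stress response 0.10, p53 0.10, S phase -0.049, immediate early 0.31, cholesterol 0.084 and mitochondrial -0.31. The estimated correlation was below the preset 0.01 for stroma (-0.037), macrophages (-0.013), erythroid (-0.13), p53 (-0.022), later spermatocytes (-0.018) and S phase (0.0092). It was above 0.01 for the others that lost their call. A correlation higher than the preset one was therefore not why the former lists lost theirs. Later spermatocytes also lost their call with no filter (-0.22), where the erythroid median was -0.21. The GC and length correction called 3356 genes (1824 rose, 1532 fell), left 3 lists called down and ended the calls of the integrated stress response (0.11), S phase (-0.037) and mitochondrial (-0.15) lists, and quantile normalization that of the integrated stress response (0.10). The cause was not tested.

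No pairing by replicate number was seen: deviations of same-numbered libraries correlated at 0.016, -0.0069 and -0.0063. With 3 libraries per group this cannot exclude pairing, on which the labels are silent. With the number as a block, 2194 genes changed and the S phase list (-0.049) was not called. The pan-germ cell list was then called (-0.11), as it was with voom, no filter and quantile normalization and without wild-type replicate 1 or Ppp6r3 cKO replicate 2 (-0.14 to -0.097). The Leydig list was called with voom, no filter and the minimum of 0.5 FPKM (0.096 to 0.10).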

Other observations

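Tests chosen only after the result was seen were those of GC content and length, of the shares of germ cells and interstitium, and of cells entering meiosis; the tests of basement membrane genes and of X-linked genes were written before their values were seen.

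Basement membrane genes were higher in Ppp6r3 cKO testis. Col4a1 (log2 fold change 0.62), Col15a1 (0.73) and Lamc3 (0.62) were noticed first. A hypothesis that basement membrane genes rose in general was then tested in the same 6 libraries, so not independently, on 20 others. Of these, 10 rose, none fell and 10 did not pass (limma), with a median of 0.29 (95% interval over genes 0.19 to 0.40). Col4a2 (0.53), Lamb1 (0.52) and Hspg2 (0.51), which encode a collagen IV chain, a laminin chain and perlecan, rose, while Lamb2 (0.0063) and Lama1 (0.018) did not pass. The camera p was 4.6e-10, and p = 0.00399 with an estimated correlation, for this list alone. The values are consistent with a rise of many of these genes, and the median was 0.26 after the GC and length correction. Which cells they came from was not tested.

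X-linked genes went down more often than autosomal genes. Of 146 X-linked genes that changed, 35 rose and 111 fell (24.0% rose), against 1316 and 1264 of autosomal genes (51.0% rose), an odds ratio of 0.303 (95% interval 0.199 to 0.451, Fisher's exact test p = 1.3e-10, 2-sided, over genes, which are not independent replicates). Genes of the X had a lower median GC content (46.3% against 50.3%), and low-GC genes fell more often in these libraries. After the GC and length correction 76 rose and 92 fell, the odds ratio was 0.679 (95% interval 0.490 to 0.938, Fisher's exact test p = 0.0169) and the median log2 fold change of X-linked genes went from -0.04 to 0.0069, that of autosomal genes from 0.0051 to 0.020. GC content and gene length, which were corrected together, may account for part of the difference or all of it. The interval after the correction lay below 1, but it treats genes as independent, so it cannot decide between these. Without Ppp6r3 cKO replicate 1, the library with the strongest GC trend, the odds ratio before the correction was 0.416. Without each other library in turn it was 0.199 to 0.265, lowest without wild-type replicate 3, and no biological explanation was tested.

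The fall of the meiotic list was weighed against technical and biological explanations. After the GC and length correction its median was -0.75 against -0.80, and the list stayed called, which argues against that bias as the whole cause. A lower share of all germ cells would lower the genes that germ cells share by as much, but the meiotic median lay 0.70 below theirs (difference -0.70, 95% interval over genes -0.99 to -0.60), though that list too was called down under 6 settings. Fewer cells entering meiosis and lower transcript levels in each such cell cannot be told apart in whole tissue: 4 of the 10 later spermatocyte genes tested fell, which either would give. Only 10 of the 20 listed met the filter, at an age when the first germ cells are entering meiosis. That list therefore says little about later cells. A delay of meiosis, which may also give these values, needs other ages and was not tested.

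For the rise of the endothelial and stroma lists, the median of their 33 genes was 0.26 after the GC and length correction against 0.29 before. A lower share of germ cells would raise every somatic type alike, but their median lay 0.33 above that of Sertoli genes (95% interval over genes 0.21 to 0.43). A larger share of the whole interstitium would raise Leydig genes as much. The pooled median lay 0.20 above theirs (interval 0.092 to 0.33), though the Leydig list was called up under 3 settings. That median pools endothelial genes (0.40) with stroma genes (0.19, quartiles 0.10 to 0.31), and macrophage genes had a median of 0.17. The Leydig quartiles, -0.043 to 0.19, overlapped those of stroma, so for stroma alone this test cannot decide. More vessels, a different piece of tissue at dissection, or higher levels per cell may each remain and were not tested.

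The immediate early list had a mean per library, relative to the mean of all 6, of -0.196 to -0.143 in wild type and 0.123 to 0.213 in Ppp6r3 cKO, and the median of immediate early genes was 0.32 after the GC and length correction.

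The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split called 2735 genes, and the highest of the other 9 called 1; 1 of the 10 splits gave as many genes. It called 14 lists with the preset correlation, and the highest other called 7; 1 of the 10 splits gave as many lists. Each of the other splits still parts the genotypes unevenly, 2 libraries against 1, so a genotype difference widens the spread within its groups. Part of such a difference also remains between the groups, so a list called there may reflect genotype. Neither few nor many calls there thus show how often calls are false. The meiotic list was called in all 9 of the other splits. The immediate early list was called in 6 of them, the endothelial list in 5, the undifferentiated spermatogonia and mitochondrial lists in 4, the ribosomal and stroma lists in 3, the macrophage and pan-germ cell lists in 2, and the later spermatocyte, erythroid, integrated stress response and glycolysis lists in 1. With an estimated correlation none of the 9 called any list, which with that wider spread does not show how often this test is wrong.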
